A study of Mus musculus with 10 samples.

How the data were processed

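RNA from the hippocampus of 10 adult mice was measured on 2-colour Agilent mouse expression arrays, 1 mouse per array. Per the labels' protocols, 5 mice were wild type (WT) and 5 carried a conditional knockout (cKO) of DLK, the dual leucine zipper kinase encoded by Map3k12. All mice received a tamoxifen diet for 3 weeks before dissection, and 750 ng of labelled cRNA of each sample was hybridised. The sample was labelled with Cy5 on every array, and a commercial RNA pool, the Universal mouse reference of Stratagene, was labelled with Cy3. No dyes were swapped. The dye effect is therefore shared by both genotypes and leaves their difference untouched, while the level of any single log ratio includes it. The sex and age in weeks of the mice, the recombinase that removed DLK and the exons it removed are not given in the sources used here.

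The scanner files hold spot intensity values that the authors obtained with Agilent Feature Extraction, version 11.0.1.1 per the file headers. These are the median pixel intensity of each spot and of its local background in both channels, not normalised. The same deposited files hold processed intensity values and their log10 ratio of Cy5 over Cy3, which per the file headers were background-subtracted and dye-normalised by that software. The authors' deposited value table holds 1 log2 value per probe and array, and limma is named in the submitters' processing notes without a version or settings. Set against log2 ratios of Cy5 over Cy3 computed from the scanner files as described next, each of its columns had a correlation across probes of at least 0.99997 and a median absolute difference of at most 0.00455. Its column medians lay between 0.0120 and 0.0204. Scale and direction were thus log2 of sample over reference, with no centring of genes. That table was used as an alternative only.

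Each array had 44397 spots, of which 1377 were control spots, and 39429 probes. Backgrounds were corrected in each channel with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50. Log2 ratios were then normalised within each array by loess with control spots at weight 0, without scaling between arrays. The plan had named mean spot signals; the files used here hold medians, so medians were used. Spots of a probe were averaged. Probes were kept where Cy5 was well above background on at least 5 of the 10 arrays, which left 28682 probes. The probe with the highest mean intensity stood for each gene, giving 23574 features. The offset pulls log ratios of dim spots towards 0, so fold changes of dim genes are understated.

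Spots that the scanner software marked as non-uniform in the spot or its background were removed before the background fit, and spots marked as population outliers were removed before averaging. The plan did not say at which step marked spots leave. Both orders were run, and both outcomes had been seen when this one was chosen. With all spots in the background fit, no gene passed the threshold, against 1 gene as reported. The difference came from WT replicate 2. On that array 3 of the spots marked for a non-uniform background had Cy3 backgrounds of 4665 to 10280, where the median over its spots was 35.5. With them, the fitted Cy3 background SD of that array was 164, and without marked spots it was 1.81. The correlation of that array with the authors' deposited values was 0.974 with all spots and 0.99999 without the marked ones. Leaving out only the spots of WT replicate 2 with a non-uniform background gave 1 gene, an alternative also chosen after the data were seen. Results under both orders are given.

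Probe accessions were matched without versions to a RefSeq gene table of mouse assembly GRCm38.p6, used for names and gene order only because the array headers name another build. This named 26581 probes, or 67.4%, and 20144 gene symbols. The other 12848 probes were tested but are not named.

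Genotypes were compared as cKO minus WT with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over the 23574 features and a threshold of adjusted p under 0.05. For Map3k12 an exact two-sided permutation test of the 5 against 5 log ratios was added. Over 34 gene lists, covering pathways, cell types, neighbours of Map3k12 and sex-linked genes, a set test was run with limma's camera procedure (cameraPR on the statistics of the same fit), with a preset correlation of 0.01, at least 5 measured members and adjustment over the lists. Camera with an estimated correlation, fry and an exact permutation test of each list's mean per animal served as alternatives. For tests that need complete data, 135 missing values in 134 features were filled with the group mean of the feature.

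The arrays lay on 3 slides. Slide 1 held 4 cKO arrays, slide 2 held 3 WT and 1 cKO array, and slide 3 held 2 WT arrays. Genotype within slide therefore rests on slide 2. Slide was tested with an F test beside genotype, and genotype was refitted with slide as a fixed block, as a random block and within slide 2.

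The comparisons, the main settings apart from the treatment of marked spots, the lists, the rule for named genes and the alternatives described as planned were fixed before the data were examined. Named by that rule are Map3k12, then the 10 largest rises and 10 largest falls among genes past the threshold. With fewer than 10 genes past it, the 5 higher and 5 lower genes with the smallest unadjusted p are also given, as values that do not pass. From each list come the members past the threshold, otherwise up to 3 members with the smallest unadjusted p. Features known only by an accession or clone are counted, not named. Within that limit, how many members are named was set after their values were seen: 3 for lists past the threshold (1 for ion channels), 2 or fewer for the 5 lists of DLK signalling and stress, and none for the rest. Esr1, Tspan2, Pcp2, Ttr and Mbp fall outside the rule and were chosen after their values were seen.

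The alternatives were other background corrections, the processed signals, other normalisations, the Cy5 channel alone, other filters and probe rules, the authors' deposited values, blocks for slide and replicate number, each array left out in turn, other variance models, array weights and a threshold of 0.1. Of the tests of explanations in the closing section, those of carry-over and of neuron share replaced earlier versions after the values of the earlier ones had been seen, and both are given there. The fits were tested on simulated data with the real genes' means and spreads. For cKO minus WT over 23574 features, 79.1% of 67 genes changed by 0.5 on the log2 scale were recovered, 98.5% of 67 genes changed by 1, and 100% of 66 genes changed by 1.5. Of 194 calls, 8 were false. The simulated spreads were independent between genes, unlike those of real tissue. The Benjamini-Hochberg threshold also loosens as more genes pass, and 194 passed in the simulation against 1 in the real data. The recovered shares can therefore overstate the power to find a few changed genes. The number of arrays limits the precision.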

Results

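The series asked how gene expression in the adult hippocampus differs between mice with and without DLK, a kinase upstream of the JNK pathway in neurons. Hippocampal RNA of 5 WT and 5 cKO mice was read against a common reference RNA, with 1 array per mouse. Median Cy5 signal per array was between 146 and 202 over a background of 29 to 31, and median Cy3 signal was between 131.5 and 141.5. Between 69.6% and 76.1% of probes were well above background in the sample channel. Correlations between arrays over all tested features ranged from 0.980 to 0.996, and no pair of arrays was identical. Values below are log2 ratios of sample over reference, differences are cKO minus WT, and each group had n = 5 mice.

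Map3k12, the targeted gene, was lower on all 5 cKO arrays than on all 5 WT arrays. Its log2 ratio was 1.92 ± 0.19 (SD, n = 5) in WT and 0.51 ± 0.24 (SD, n = 5) in cKO hippocampus. It fell by 1.41 on the log2 scale (SE 0.12, limma adjusted p = 0.00101), to 37.6% of the WT level with a 95% interval of 31.4% to 44.9%. The spot was dim in Cy3 and the offset pulls its ratio towards 0, so these percentages depend on the processing. The difference was −1.58 with an offset of 16, −1.78 with plain background subtraction and −1.81 with the processed signals. It was −1.25 with all spots in the background fit. The exact two-sided permutation test gave p = 0.00794, the smallest value that 5 against 5 arrays allow. The array carried 1 Map3k12 probe, for transcript NM_001163643, and whether it lies in the deleted exons is not given in the sources used here. Cy5 signal of this spot was 495 to 746 on WT arrays and 157.5 to 390.5 on cKO arrays. On cKO replicate 2 the Cy3 reference signal of the spot was 314, against 102.5 to 128 on the other 9 arrays. Its Cy5 signal, 390.5, was the highest of the 5 cKO arrays, and its log ratio was 0.11. With slide as a block, the difference rested on this array and was −1.80 (limma adjusted p = 0.0150). Within slide 2 alone it was also −1.80. The high Cy3 signal lowers the log ratio of this array, so −1.80 can overstate the fall. On slide 2 the Cy5 signal was 390.5 on the cKO array and 550 to 614 on the WT arrays. Without cKO replicate 2 the difference was −1.31. With the Cy5 channel alone it was −1.18 (adjusted p = 0.0650).

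**Figure D1:**
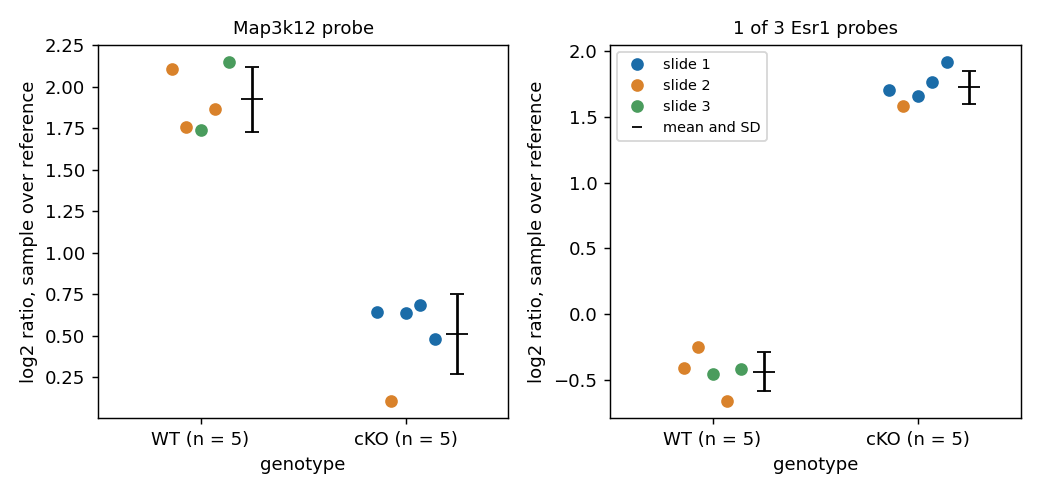
Log2 ratio of sample over reference on each array, by genotype, for the Map3k12 probe (left) and for 1 of the 3 Esr1 probes (right). Points are single mice coloured by slide, the bars show the mean and SD of 5 mice, and the cKO mean was 0.51 against 1.92 for Map3k12 and 1.73 against −0.44 for the Esr1 probe.

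No other gene passed the threshold among the 23574 features tested, of which 16268 had a gene symbol. At an unadjusted p under 0.05 there were 913 features, 677 higher and 236 lower in cKO, where 1178.7 would arise with no difference at all. That number was 2006 with array weights, 890 with slide as a fixed block and 605 with median centring. It was 1894 with slide as a random block, where the fitted correlation within slides was −0.129. A negative value treats arrays of 1 slide as less alike than arrays of different slides, so 1894 is no sign of more change. The count of 1 rested on the treatment of marked spots on WT replicate 2. With all spots in the background fit no gene passed in limma, 858 features had an unadjusted p under 0.05, and Map3k12 was at −1.25 with adjusted p = 0.970. Without cKO replicate 4 the count was 2, with Pcp2, a gene chosen here after its value was seen, as the added gene. The 95% interval of the fold change lay within 1.5-fold either way for 98.4% of features, and it reached 2-fold for 60 features. These intervals are of ratios that the offset pulls towards 0, for 1 probe per gene. They do not bound the true change of dim genes or of other probes. For Map3k12 the SE was 0.119 here and 0.186 with plain background subtraction.

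The 5 genes with higher values and the smallest unadjusted p were Slc52a3, a riboflavin transporter (0.31, SE 0.06), Lama1, a laminin chain of basement membranes (0.36, SE 0.07), the transcription factors Zic1 (0.64, SE 0.14) and Sox18 (0.31, SE 0.07), and Plxnb3, a semaphorin receptor (0.33, SE 0.07). None of them passed, each with an adjusted p of 0.99999. The 5 genes with lower values were Dpyd, which encodes the enzyme that starts pyrimidine breakdown (−0.67, SE 0.12, adjusted p = 0.801), the olfactory receptor gene Olfr1056 (−0.30, SE 0.07), the neuroglobin gene Ngb (−0.38, SE 0.09), the zinc finger gene Zfp811 (−0.26, SE 0.07) and the ion channel gene Trpa1 (−0.29, SE 0.08). The last 4 had adjusted p = 0.99999. Olfr1056 was well above background on 4 of the 5 cKO arrays.

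Among 4118 genes with several kept probes, 1 gene had probes that moved in opposite directions at an unadjusted p under 0.05. When all 28682 kept probes were tested, 3 passed, of which 2 were higher and 1, that of Map3k12, was lower. The 2 others belong to Esr1 and Tspan2 and were chosen after their values were seen. Esr1 encodes oestrogen receptor alpha. Its probe A_55_P2030883 was well above background on all 5 cKO arrays and on 0 of the 5 WT arrays, with Cy5 signals of 277 to 385 and 34.5 to 53. The probe passed with adjusted p = 8.2e-08. Its fitted log2 difference ranged from 2.02 to 5.50 over 32 alternatives and is no measure of its size, because the WT signals were near background. On slide 2 the cKO array had a Cy5 signal of 345 and the 3 WT arrays had signals of 34.5 to 53. The Esr1 probe that stood for the gene, A_52_P237077, differed by −0.09 (SE 0.09), and the other Esr1 probe was not well above background on any array. Tspan2, a gene of oligodendrocytes, had a difference of 0.56 (SE 0.07, adjusted p = 0.0176) at probe A_55_P2028837 and of 0.29 (SE 0.10) at the brighter probe, and the first of these values kept its direction in all 32 alternatives (0.29 to 2.38) and passed in 17.

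Genes of the choroid plexus and ependyma, the secretory and ciliated epithelia of the ventricles, were higher in cKO samples. All 22 measured members had higher values, by a mean of 0.75 on the log2 scale (camera adjusted p = 3.2e-21). With an estimated correlation the adjusted p was 0.177. Kcnj13, a potassium channel of this epithelium, had 3.03 times the WT level (log2 1.60, SE 0.38), the coagulation factor gene F5 2.14 times (95% interval of the log2 difference 0.54 to 1.65) and the chloride channel gene Clic6 2.15 times (0.44 to 1.77). Clic6 had the opposite sign with the scanner software's processed signals. None of the 22 passed over all genes, and 13 passed when adjusted over the list alone. The list mean per mouse was 0.80 ± 0.34 (SD, n = 5) in WT and 1.55 ± 0.52 (SD, n = 5) in cKO hippocampus, with an exact permutation p of 0.0238 and an adjusted p of 0.135 over the 34 lists. The cKO value exceeded all WT values in 3 of 5 mice, and with slide as a block or within slide 2 the difference was 0.91.

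Oligodendrocyte genes, most of which encode myelin proteins, were also higher in cKO samples. Of 23 members 20 had higher values, with a mean difference of 0.32 (camera adjusted p = 6.4e-19; adjusted p = 0.177 with an estimated correlation). The leading members were Adamts4, a metalloprotease (0.45, SE 0.10), Hapln2, a matrix linker at nodes of Ranvier (0.42, SE 0.10), and Mag, the myelin-associated glycoprotein (0.51, SE 0.13). None passed over all genes, and 15, all with higher values, passed when adjusted over the list alone. The list mean per mouse was 2.93 ± 0.18 (SD, n = 5) in WT and 3.25 ± 0.13 (SD, n = 5) in cKO samples, and 4 of 5 cKO mice exceeded all WT mice (exact permutation p = 0.0159, adjusted p = 0.135). With slide as a block or within slide 2 the difference was 0.29. Choroid plexus genes were higher in the same samples by 0.75. The oligodendrocyte and choroid plexus lists share the gene Enpp2 and are not independent results. In both lists cKO replicates 5, 2 and 4 were the highest cKO mice, and WT replicate 5 was the lowest mouse. Genes of oligodendrocyte precursors had a mean difference of 0.09 (camera adjusted p = 0.00497; adjusted p = 0.215 with an estimated correlation), led by Olig1 (0.31, SE 0.08), Cspg5 (0.21, SE 0.10) and Gpr17 (0.12, SE 0.07), and 1 of 15 passed when adjusted over the list alone. Within slide 2 the difference of the precursor list was 0.03, and without WT replicate 5 the camera adjusted p was 0.0858. With the Cy5 channel alone the precursor list was at 0.04 (camera adjusted p = 0.106), and with array weights at 0.06 (0.184).

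**Figure D2:**
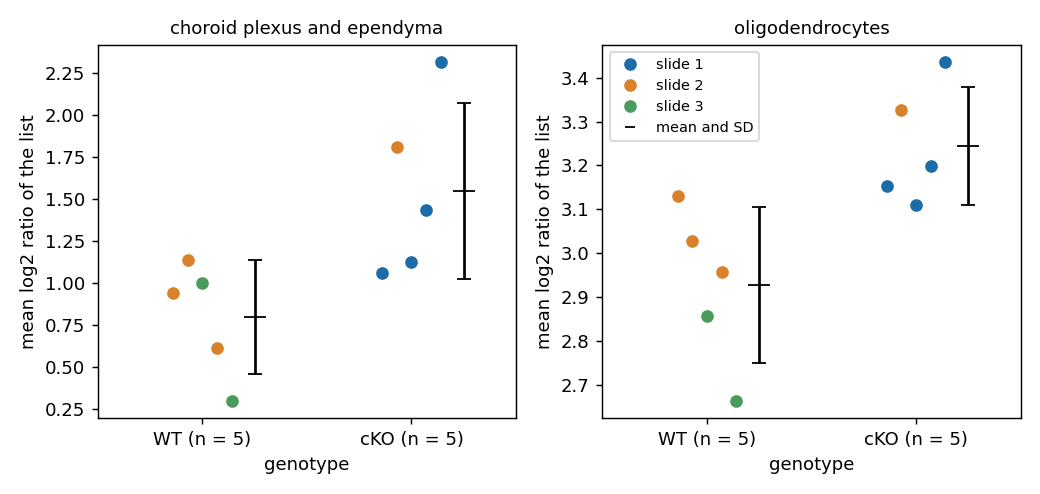
Mean log2 ratio of the choroid plexus and ependyma list (left, 22 genes) and of the oligodendrocyte list (right, 23 genes) in each mouse, by genotype. Points are single mice coloured by slide, the bars show the mean and SD of 5 mice, and of the 5 cKO mice 3 lie above all WT mice on the left and 4 on the right.

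Other cell types of the tissue and its surroundings shifted less. Endothelial and pericyte genes had a mean difference of 0.12 (camera adjusted p = 0.000489; adjusted p = 0.177 with an estimated correlation), with Vwf (0.30, SE 0.08), Emcn (0.21, SE 0.07) and Esam (0.23, SE 0.08) in the lead, and 0.04 within slide 2 (adjusted p = 0.699). Inhibitory interneuron genes had a mean difference of 0.07 (camera adjusted p = 0.00206; adjusted p = 0.177 with an estimated correlation) and 0.08 within slide 2, with Gad2, a GABA-synthesising enzyme, at 0.27 (SE 0.09), Maf at 0.18 (SE 0.07) and Slc32a1, the vesicular GABA transporter, at 0.12 (SE 0.06). The thalamus list had a mean difference of 0.16 (camera adjusted p = 0.00347; adjusted p = 0.225 with an estimated correlation) and 0.13 within slide 2. Zic1 led it, followed by Tnnt1 (0.40, SE 0.18) and Lef1 (0.15, SE 0.07), and Zic1 is a gene of several brain regions and of the meninges. Genes of meninges and fibroblasts differed by 0.10 (camera adjusted p = 0.0171; adjusted p = 0.596 with an estimated correlation) and by 0.02 within slide 2, with Col1a1 (0.24, SE 0.07), Slc13a4 (0.75, SE 0.22) and Aldh1a2 (0.28, SE 0.12). Blood genes differed by 0.09 (camera adjusted p = 0.0316; adjusted p = 0.742 with an estimated correlation), with Hbb-bt (0.16, SE 0.07), Camp (0.15, SE 0.07) and Slc4a1 (−0.11, SE 0.06). Astrocyte genes differed by 0.07 (camera adjusted p = 0.0386; adjusted p = 0.868 with an estimated correlation), with Mlc1 (0.20, SE 0.10), Slc7a10 (0.15, SE 0.08) and Fjx1 (0.13, SE 0.07). Within slide 2 blood genes were at −0.06. Astrocyte genes passed in the opposite direction, at −0.21, with slide as a block (camera adjusted p = 0.000159), and had the same value within slide 2. Both rest on 1 mouse, cKO replicate 2, whose list mean was 3.62, against 3.79 to 3.86 in the WT mice of slide 2. WT replicate 5 on slide 3 was lower still, at 3.52. The p-value therefore does not measure the spread between cKO mice. Adjusted over the list alone, 1 thalamus gene and 2 meningeal genes passed, and no gene of the other 4 lists did. With the Cy5 channel alone the interneuron list was at −0.00100 and the astrocyte list at −0.0360. Median centring moved the median of all genes to −0.06 and the astrocyte list to −0.0123, still higher relative to other genes but not past the threshold (adjusted p = 0.163). The calls of 3 lists rested on single mice. Meningeal genes had adjusted p = 0.0595 without WT replicate 1, 0.105 without WT replicate 5, 0.0539 without cKO replicate 4 and 0.287 without cKO replicate 5. The mean of meningeal genes was 0.05 in the last case. Blood genes had adjusted p = 0.114 without WT replicate 2, 0.641 without WT replicate 5 (at 0.03), 0.122 without cKO replicate 3 and 0.230 without cKO replicate 5 (at 0.05), and were at 0.14 without WT replicate 4 (0.000797). Processing mattered as well. Blood genes had camera adjusted p = 0.102 with plain background subtraction, 0.0675 with the processed signals and 0.199 with the mean of a gene's probes. It was 0.327 with the Cy5 channel alone and 0.482 with array weights, where meningeal genes had 0.238. Astrocyte genes were at 0.01 without WT replicate 5 (adjusted p = 0.988), 0.05 without cKO replicate 3 (0.370), 0.01 without cKO replicate 5 (0.862) and 0.13 without cKO replicate 2 (0.000179).

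In the fit without slide, the lists of hippocampal principal cells, newborn neurons, neocortex, striatum and microglia did not pass. The mean difference was −0.05 for dentate granule cells (camera adjusted p = 0.124), 0.01 for CA1 pyramidal cells (0.812 by the same test), 0.03 for CA2 and CA3 pyramidal cells (0.398), 0.03 for newborn neurons and progenitors (0.572), 0.06 for the neocortex list (0.196) and −0.07 for the striatum list (0.258). Microglial genes differed by 0.05 (camera adjusted p = 0.258). No member of these 7 lists passed when adjusted over the list alone. With slide as a block, where the difference rests on cKO replicate 2, camera passed dentate granule cells at −0.21 (adjusted p = 0.000947), neocortex at 0.23 (0.000115) and microglia at −0.16 (0.000831), the last in the opposite direction. Within slide 2 the values were the same, with adjusted p = 0.000122, 0.00149 and 0.000122. Microglia passed at 0.09 without cKO replicate 2 (adjusted p = 0.0106). Dentate granule cells also passed at −0.08 without WT replicate 4 (adjusted p = 0.00874), −0.08 without cKO replicate 1 (0.0199), −0.12 without cKO replicate 4 (0.000108), −0.11 with the Cy5 channel alone (0.00381) and −0.06 with the mean of a gene's probes (0.0469). The neocortex list passed at 0.10 without WT replicate 1 (adjusted p = 0.0222), 0.09 without cKO replicate 4 (0.0331), 0.01 with median centring (0.0325) and 0.22 with all spots in the background fit (0.0178). In that last fit CA2 and CA3 pyramidal cells passed at 0.16 (adjusted p = 0.0242). The striatum list changed sign and passed without WT replicate 1, at 0.12 (adjusted p = 0.0456), and passed at −0.13 without WT replicate 2 (0.0396) and at −0.20 with the Cy5 channel alone (0.00241).

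Synaptic and axonal genes were slightly higher in cKO samples, in the camera test with the preset correlation. In the exact permutation test of list means per mouse none of these 5 lists passed after adjustment. The unadjusted permutation p was 0.0159 for axon and microtubule genes and 0.0556 for the postsynaptic density. It was 0.222 for glutamate receptors, 0.262 for the presynaptic list and 0.365 for ion channels. Of 29 genes of the presynaptic vesicle cycle 25 had higher values, with a mean of 0.09 (camera adjusted p = 4.6e-05; adjusted p = 0.504 with an estimated correlation). Their leading members were Syt2 (0.25, SE 0.07), well above background on 3 of 5 WT and 2 of 5 cKO arrays, Cplx1 (0.18, SE 0.07) and Rims1 (0.17, SE 0.06). Axon and microtubule genes had a mean difference of 0.08 (camera adjusted p = 4.6e-05; adjusted p = 0.177 with an estimated correlation), with 25 of 30 higher. It was led by the neurofilament genes Nefh (0.22, SE 0.05) and Nefm (0.24, SE 0.08) and by Crmp1 (0.18, SE 0.06), and 1 member passed when adjusted over the list alone. Postsynaptic density genes differed by 0.08 (camera adjusted p = 0.00113; adjusted p = 0.312 with an estimated correlation), with Dlgap1 (0.17, SE 0.06), Camk2b (0.14, SE 0.06) and Kalrn (0.14, SE 0.06). Ionotropic glutamate receptor genes differed by 0.10 (camera adjusted p = 0.00113; adjusted p = 0.551 with an estimated correlation), with Gria3 (0.23, SE 0.07), Gria4 (0.20, SE 0.08) and Grik1 (0.19, SE 0.09). Voltage-gated ion channel genes differed by 0.09 (camera adjusted p = 0.0122; adjusted p = 0.843 with an estimated correlation), with Kcna1 at 0.31 (SE 0.10). Within slide 2 these 5 lists, in the order given, differed by 0.22, 0.10, 0.02, 0.18 and 0.17. Without cKO replicate 1 the presynaptic list was at 0.06 (adjusted p = 0.00885), glutamate receptors at 0.06 (0.0686) and ion channels at 0.05 (0.216). The ion channel list was also at 0.07 without WT replicate 1 (adjusted p = 0.136), 0.08 without WT replicate 3 (0.0627), 0.06 without WT replicate 4 (0.144), 0.06 without cKO replicate 4 (0.292) and 0.16 without WT replicate 5 (4.9e-07). Without background subtraction the ion channel list was at 0.05 (camera adjusted p = 0.179). With the Cy5 channel alone none of these 5 lists passed. The presynaptic list was then at 0.02 (adjusted p = 0.519), axon and microtubule at 0.03 (0.458), postsynaptic density at −0.00705 (0.754), glutamate receptors at 0.01 (0.520) and ion channels at −0.00271 (0.864). Median centring moved the median of all genes to −0.06 and the axon list to −0.00911, still higher relative to other genes and past the threshold (adjusted p = 0.0367). The oligodendrocyte and choroid plexus lists were higher in the same samples.

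**Figure D3:**
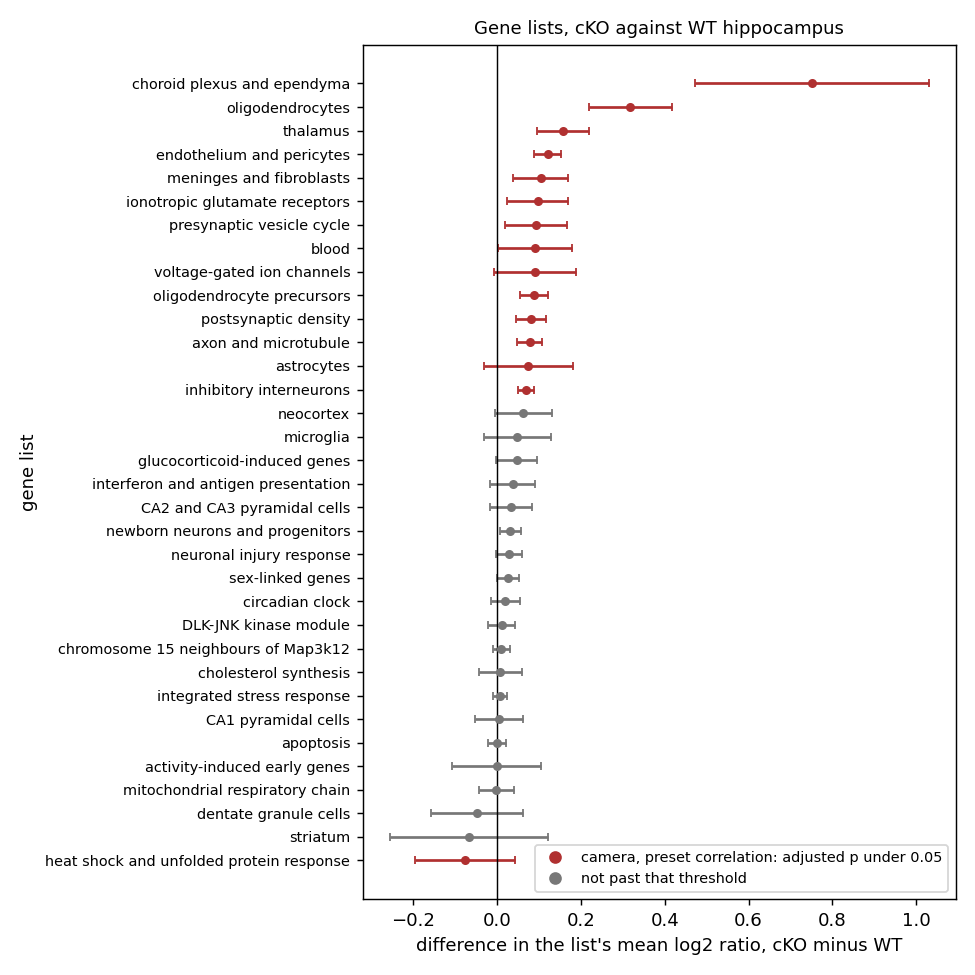
Difference between cKO and WT hippocampus in the mean log2 ratio of each of the 34 gene lists, with its SE over 5 and 5 mice as bars. Red marks the 15 lists with a camera adjusted p under 0.05 at the preset correlation, of which choroid plexus (0.75) and oligodendrocytes (0.32) lie farthest right.

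The gene lists around the DLK pathway did not pass in the fit without slide. The DLK-JNK kinase module, without Map3k12, had a mean difference of 0.01 over 20 genes (camera adjusted p = 0.799). The largest contributions by unadjusted p were Mapk10, the neuronal JNK3 gene (0.16, 95% interval 0.03 to 0.30), and Jun, a target of JNK (−0.42, 95% interval −0.80 to −0.03), neither past the threshold. The neuronal injury response list differed by 0.03 over 21 genes (camera adjusted p = 0.128), with Ngfr at 0.17 (SE 0.06). The integrated stress response list differed by 0.01 over 22 genes (camera adjusted p = 0.913), with Ddit4 at −0.20 (SE 0.09) and Mthfd2 at 0.12 (SE 0.05). Apoptosis genes differed by 0.00 over 23 genes (camera adjusted p = 0.855), with Apaf1, a part of the apoptosome, at −0.27 (SE 0.07) and Bmf at 0.19 (SE 0.09). Activity-induced early genes differed by −0.00 over 28 genes (camera adjusted p = 0.952), with Btg2 at −0.19 (SE 0.07) and Dusp1 at −0.30 (SE 0.17). With slide as a block and within slide 2, both resting on cKO replicate 2, the early genes passed at 0.34 (adjusted p = 1.4e-08 and 1.1e-08), and without that mouse they passed in the opposite direction, at −0.08 (0.0173). The injury response list passed at 0.04 without WT replicate 4 (adjusted p = 0.0391) and at 0.05 without cKO replicate 4 (0.0331). In these 5 lists no member passed over all genes or when adjusted over the list alone.

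Heat shock and unfolded protein response genes were lower in cKO samples by a mean of 0.08, a difference of −0.08, with 19 of 21 lower (camera adjusted p = 0.00528; adjusted p = 0.832 with an estimated correlation). Hspa1a was at −0.18 (SE 0.16), Pdia6 at −0.18 (SE 0.16) and Xbp1 at −0.19 (SE 0.18). The list passed in the opposite direction with slide as a block, at 0.16 (camera adjusted p = 0.0278). It had the same value within slide 2, and both rest on cKO replicate 2. Without WT replicate 2 the difference was 0.00 (adjusted p = 0.791). It was −0.05 without WT replicate 3 (adjusted p = 0.0675), −0.05 without cKO replicate 1 (0.0628) and −0.04 without cKO replicate 5 (0.182). It was −0.13 without WT replicate 1 (adjusted p = 5.5e-05), −0.12 without WT replicate 4 (3.7e-05) and −0.13 without cKO replicate 2 (8.4e-05). The remaining lists did not pass in the fit without slide. Their mean differences were 0.05 for glucocorticoid-induced genes (camera adjusted p = 0.308), 0.04 for interferon and antigen presentation (0.326), −0.00 for the mitochondrial respiratory chain (0.971), 0.02 for the circadian clock (0.855), 0.01 for cholesterol synthesis (0.867), 0.03 for sex-linked genes (0.894) and 0.01 for the chromosome 15 neighbours of Map3k12 (0.855). The respiratory chain list passed at −0.09 with slide as a block (camera adjusted p = 0.0134). It had the same value within slide 2, and both rest on cKO replicate 2. With median centring the respiratory chain list passed at −0.10 (camera adjusted p = 0.01001). The interferon list passed at 0.04 with the Cy5 channel alone (adjusted p = 0.0330) and at 0.06 without WT replicate 1 (0.0433). No member of these 8 lists passed when adjusted over the list alone. Mean, median and camera's direction differed in sign for the neighbours of Map3k12, apoptosis, circadian clock, cholesterol synthesis, integrated stress response, early genes and respiratory chain lists, all with mean differences near 0.

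In the fit that held genotype and slide together, no gene passed the F test of limma over the 3 slides, and 1112 of 23574 features had an unadjusted p under 0.05, where 1178.7 would arise by chance. With the Cy5 channel alone 185 genes differed between slides. In the fit with slide, 1 gene passed for genotype, Map3k12, and 890 features had an unadjusted p under 0.05.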

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

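The counts of genes and lists over other splits of the animals were planned before the data were examined. The tests of the choroid plexus, oligodendrocyte and Esr1 patterns were chosen only after the results were seen, and those of carry-over and of neuron share were also revised after the values of a first version had been seen.

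For the genes that differed between cKO and WT, 12 of 100 splits of the 10 mice into 5 and 5 gave at least 1 gene. The real split was included, so chance cannot be excluded for a count of 1. That count ignores which gene passed. In the real split it was Map3k12, the targeted gene, lower on all 5 cKO arrays than on all 5 WT arrays (exact permutation p = 0.00794). The highest of the other splits gave 2959 genes, for WT replicates 1, 3 and 4 with cKO replicates 3 and 5 against the rest, a grouping that follows neither genotype nor slide and points to a structure among the animals. For the gene lists, 4 of 100 splits gave at least 15 lists, the real one included, and the highest other gave 16. The real split was thus among the highest by that count, but the count cannot exclude chance. It rests on camera with the preset correlation. No list passed with an estimated correlation, with fry or with the permutation test of list means. The splits also ignored slide, and slide 1 held 4 of the 5 cKO arrays.

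Choroid plexus and ependyma genes were higher in cKO samples by 0.75 on the log2 scale. The difference with slide as a block was 0.91. It rests on the single cKO array that shared a slide with WT arrays, 0.67 above the highest of them. That 1 array cannot decide about slide, which stays open. On slide 1, cKO replicates 1 and 3 (1.06 and 1.12) lay below WT replicate 2 (1.13). Unequal carry-over of choroid plexus at dissection is a candidate explanation. With group means removed, the members rose and fell together from mouse to mouse. Their mean pairwise correlation of 0.70 lay at percentile 100 of 10000 random lists, although shared regulation within a cell type would give this too. Camera's estimated correlation was also high for astrocytes (0.63) and microglia (0.40), and low for endothelium and pericytes (0.06), so this test cannot decide. In the first version of this test Ttr, the most abundant gene of this epithelium, at 4.28 ± 0.81 (SD, n = 5) in WT and 5.43 ± 0.35 (SD, n = 5) in cKO samples, followed the mean of the other members with r = 0.77 (permutation p = 0.00735; rho = 0.89, p = 0.00114; r = 0.80 without the 2 farthest mice), and an effect of genotype on this tissue stays open, untested.

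Oligodendrocyte genes were higher in cKO samples by 0.32. A lower share of neurons as the whole cause is argued against because oligodendrocyte genes exceeded microglial genes by 0.27 more in cKO than in WT mice (SE 0.08, exact permutation p = 0.00794), while the first version of that test, the presynaptic list, was at 0.09 (SE 0.07). The difference with slide as a block was 0.29. It rests on the single cKO array of slide 2, 0.20 above the highest WT array there. That 1 array cannot decide about slide, which stays open. On slide 1, cKO replicate 3 (3.11) lay below WT replicate 1 (3.13). Unequal carry-over of white matter is a candidate explanation that was not decided. The mean pairwise correlation of the 22 members without missing values, 0.41, lay at percentile 100 of random lists, with the same reservation. Camera's estimated correlation was as high or higher for astrocytes (0.63) and dentate granule cells (0.52). It was 0.40 for microglia and 0.06 for endothelium and pericytes. A high value is thus not particular to carry-over of white matter. The first version of the carry-over test spoke against it. Mbp, an abundant myelin gene at −0.09, followed the other members with r = 0.07 (permutation p = 0.855, rho = 0.10, p = 0.784, r = 0.08 without the 2 farthest mice). That version was replaced because 1 gene with a high baseline excludes nothing, a limit that also holds for Ttr above. A change in oligodendrocytes with genotype stays open, untested.

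Of the 3 Esr1 probes, 1 was bright on the cKO arrays alone. Higher expression of the whole Esr1 transcript is argued against by the Esr1 probe that was well above background on all arrays, at −0.0858 (SE 0.0852). The bright probe differed by 2.02 with slide as a block (adjusted p = 0.00170) and within slide 2 (adjusted p = 0.0556), and it was bright on cKO arrays of slides 1 and 2 and dark on WT arrays of slides 2 and 3, which speaks against slide as the whole cause, but the gap of 1.83 on slide 2 comes from 1 cKO array and from WT arrays at background, so slide stays open. A candidate explanation is a transgene with an oestrogen receptor part, as in tamoxifen-inducible recombinases, carried by the cKO mice alone, and the probe was bright or dark as this needs on 10 of 10 arrays, a pattern that was known before the test. The recombinase, the genotype of the controls for it and the position of the probe are not given in the sources used here, so an effect of DLK loss on part of the Esr1 transcript stays open, untested.

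Single values stood apart from the others of their group in 10 of 98 groups, where chance gives about 4.9. The groups share mice and hold lists that move together, so 1 mouse can be counted several times and the excess is no test. The Cy3 reference signal of the Map3k12 spot was 314 on cKO replicate 2, against 102.5 to 128 on the other cKO arrays. Against the mean of the other 9 arrays, with the array's median difference removed, this spot was 1.498 higher in Cy3 on the log2 scale, and its 48 neighbouring spots were higher by a median of 0.08 and at most 2.59. Its Cy5 signal was 0.88 higher than the mean of the other cKO arrays. Lama1 was at 1.81 in WT replicate 4, against 1.93 to 1.97 in the other WT mice. WT replicate 5 stood apart in 4 list means, with 1.68 for the DLK-JNK kinase module against 1.57 to 1.59, 3.76 for ion channels against 3.35 to 3.43, 3.52 for astrocytes against 3.79 to 3.86 and 1.08 for microglia against 1.33 to 1.41. The striatum list was at 3.36 in WT replicate 1, against 2.37 to 2.56. In cKO replicate 5 the interferon list was at −1.79, against −1.96 to −1.92, and the neighbours of Map3k12 at −0.99, against −1.08 to −1.06. The neocortex list was at 2.88 in cKO replicate 2, against 2.61 to 2.69.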

How the results depend on the processing

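Normexp on all spots, normexp without only the marked background spots of WT replicate 2, and the permutation test of list means were added after seeing the data. The cause was not tested unless one is given. Map3k12 kept its direction in all 32 alternatives, between −1.81 and −1.18, with adjusted p from 0.000268 to 0.970, and its side of the threshold in 28. Without 1 mouse at a time it lay between −1.46 and −1.31. It missed the threshold with plain background subtraction (−1.78), with the Cy5 channel alone (−1.18), within slide 2 (−1.80) and with normexp on all spots (−1.25). The count of genes was 0 with plain subtraction, within slide 2 and with normexp on all spots, 3 with all probes, 2 with the mean of a gene's probes, and 1 to 2 without 1 mouse at a time. With the Cy5 channel alone it was 1, Esr1 and not Map3k12. Within slide 2 there were fewer arrays, 3 WT and 1 cKO, with the lone cKO array assumed to vary like the others. With normexp on all spots the cause was the background fit of WT replicate 2, whose Cy3 SD rose from 1.81 to 164.

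The count of 15 lists was 8 with the Cy5 channel alone, and only 5 of those 8 were among the 15. It was 0 with an estimated correlation, with fry and with the permutation test of list means. Without 1 mouse at a time it was 11 to 17. Of the 15 lists, 8 passed without each mouse in turn and 7 with slide as a block. Genes that differed between slides numbered 1 without the filter on dim probes, 3 without background subtraction and 185 with the Cy5 channel alone. With the replicate number as a block, Map3k12 was at −1.41 (adjusted p = 0.0165), and 0 of 5 WT mice correlated best with the cKO mouse of the same number.

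The lists that passed under an alternative alone are given with their values in the results. Signs reversed as follows. With the processed signals Clic6 was at −0.21. With the Cy5 channel alone Syt2 was at −0.0768, Rims1 at −0.00117, Mlc1 at −0.0271, Fjx1 at −1.55e-05, Gpr17 at −0.00570, and the postsynaptic list at −0.00705, ion channels at −0.00271 and astrocytes at −0.0360. With the mean of a gene's probes Camp was at −0.0812. With slide as a block, and with the same values within slide 2, Dusp1 was at 0.23, Hspa1a at 0.27, Pdia6 at 0.12, Xbp1 at 0.31, Mlc1 at −0.15, Slc7a10 at −0.0730, Fjx1 at −0.0450, Tnnt1 at −0.0247, Hbb-bt at −0.00374, and the heat shock list at 0.16, blood at −0.0637 and astrocytes at −0.21. With array weights astrocytes were at −0.00333. List means also changed sign, with the direction of the test kept, for axon and microtubule (−0.00911) and astrocytes (−0.0123) with median centring, for interneurons with the Cy5 channel alone (−0.00100) and for heat shock without WT replicate 2 (0.00199). Signal over background limits dim genes, whose ratios the offset pulls towards 0.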

Other observations

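The largest axis of variation among the 10 hippocampi did not separate the genotypes. The first principal component held 35.5% of the variance (exact permutation p for genotype = 0.921). All relations below, 34 in the family, were chosen after the data were seen and use the same data as the component, whose sign is arbitrary. The mean of the DLK-JNK kinase module followed it with r = 0.90 (permutation adjusted p = 0.00416; rho = 0.88, adjusted p = 0.0114; r = 0.87 without the 2 farthest mice). Voltage-gated ion channels followed it with r = 0.90 (permutation adjusted p = 0.00416; rho = 0.78, adjusted p = 0.0584; r = 0.91 without those mice). Astrocyte genes ran the opposite way with r = −0.89 (permutation adjusted p = 0.00416; rho = −0.90, adjusted p = 0.0114; r = −0.73), as did microglial genes with r = −0.88 (permutation adjusted p = 0.00416; rho = −0.89, adjusted p = 0.0114; r = −0.65) and respiratory chain genes with r = −0.88 (permutation adjusted p = 0.00796; rho = −0.93, adjusted p = 0.0114; r = −0.87). Apoptosis genes also ran the opposite way, with r = −0.85 (permutation adjusted p = 0.0101, rho = −0.88, adjusted p = 0.0114, r = −0.76 without those mice). The blood, presynaptic, interferon and glutamate receptor lists passed by r (permutation adjusted p of 0.0159 to 0.0225) but not by rho. Slides held 4, 4 and 2 arrays, too few for a correlation within a slide.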
